A study of Mus musculus with 22 samples.

How the data were processed

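Gene expression was measured in total RNA from the livers of 22 female C57BL/6J mice, 12 weeks old, on Affymetrix MoGene 2.0 ST arrays, 1 array per mouse. The labels place the mice in 4 groups by genotype and diet: wild type on chow (WT_chow, n = 5), wild type on UDCA (WT_UDCA, n = 6), Cyp2c70 knockout on chow (KO_chow, n = 5) and Cyp2c70 knockout on UDCA (KO_UDCA, n = 6). UDCA is ursodeoxycholic acid, a hydrophilic bile acid, given at 0.1% of the diet for 7 weeks from the age of 5 weeks. Mice were numbered within a group in the order of their records, so a replicate number names a mouse and pairs nothing.

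Per the labels, the authors deposited intensity values summarised by RMA with a probe-level model and reported on the unlogged scale. The values ran from 1.66 to 10284, and the median intensity of an array lay between 28.7 and 31.1 in every group. The submitters' processing notes name RMA without a version, and the genome build is not given in the sources used here. The table held 24973 rows with numeric identifiers. The platform annotation gave 24015 of them exactly 1 gene symbol and left 958 without a symbol, and these 958 entered no named result. Of the 24015 rows, 23922 were matched by gene identifier to the RefSeq table of assembly GRCm38.p6, which changed 0 symbols and was used for names only. For the 4 symbols that stood on several rows, the row with the highest mean log2 value was kept, which left 24011 genes. No array was left out, and 0 columns lacked a sample.

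Intensities were converted to log2 without a pseudocount and without a filter on dim genes. A linear model with a mean per group was fitted to all 22 arrays with limma 3.58.1 in R 4.3.3 (with version 1.17.8 of data.table), with moderated variances shared across the 4 groups. The 6 comparisons were KO_chow vs WT_chow, KO_UDCA vs KO_chow, KO_UDCA vs WT_UDCA, KO_UDCA vs WT_chow, WT_UDCA vs WT_chow and the genotype by diet interaction. P-values are two-sided limma p-values with Benjamini-Hochberg adjustment over all 24011 genes of a comparison, and a gene was called changed at an adjusted p below 0.05. Errors of log2 fold changes are standard errors from the fit (SE). The arrays are biological replicates, so p-values measure the spread between mice. The median SD of a gene was 0.193 log2 units in KO_chow and 0.168 in WT_chow, so a variance shared by the groups is not the variance of each. Single genes can differ more than these medians. Mmp12 ran from 8.459 to 11.01 in KO_chow and from 4.534 to 5.419 in WT_chow, whereas Cyp2c70 ran from 10.52 to 10.83 and from 11.28 to 11.62. For genes more spread in KO_chow, the shared variance can make the SE and p-value of a comparison with KO_chow too small. The number of arrays limits the precision: in the comparison of KO_chow with WT_chow, a fit to simulated data for 24011 genes recovered 58.2% of genes changed by 0.5 log2, 98.5% of those changed by 1 and 100% of those changed by 2, with 13 false calls among 184. The simulation changed 67, 67 and 66 genes by these amounts, with the same spread in every group. The adjusted cut-off depends on the number of calls, which was 3295 in the data, so these shares do not carry over to the real comparison.

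The 34 gene lists cover bile acid metabolism, cell type markers, inflammation, fibrosis, stress, the cell cycle and hepatocyte functions, and hold 478 different genes, of which 36 matched no row. Each list was tested against all other genes with limma camera at a preset correlation between genes of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 34 lists of a comparison. Camera with a correlation estimated from the arrays was the alternative and is the stricter test. Some genes stand on more than 1 list.

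The design, the gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule names Cyp2c70 and its Cyp2c relatives, the 12 largest rises and 8 largest falls in the first 2 comparisons and 6 of each in the others among changed genes whose groups do not overlap in any array (the overlap was not considered for the interaction), up to 3 members of each list with the largest changes (or the member with the smallest p), and Cyp7a1, Cyp8b1, Nr0b2, Abcb11, Slc10a1, Krt7, Krt19 and Col1a1. Predicted genes, Rik clones, small RNAs, receptor clusters and immunoglobulin or T cell receptor segments were left out of the largest changes but counted in all totals. The rule names 203 genes. The text draws on a set of 83, picked after the values were seen and before any alternative was computed, and this set was not altered when alternatives ended calls in it. It holds 1810053B23Rik, which lies outside the rule. The report also names Cyp2c38, Cyp2c40 and Cyp2c67, which the rule holds and the set does not, because alternatives ended their calls. The alternatives were run on every gene the rule names and on 1810053B23Rik, except that the filter on dim genes described below left some out. In KO_chow vs WT_chow these included Ch25h, Retnlg, S100a8, Slc7a11 and Asns.

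For the genes changed on chow, the genotype effect under UDCA was regressed on the effect on chow by least squares through 0. The 2 effects share no arrays. An interval came from 1000 bootstrap draws of arrays within groups, and the slope was recomputed with genes selected on 3 KO_chow and 3 WT_chow arrays and estimated on the rest. The comparisons that share the KO_chow arrays were set beside 20 simulations of unchanged groups. After the data were seen, 20 simulations were added in which both knockout groups kept the KO_chow means, and the sign of the change was also taken with genes selected on 3 KO_chow arrays and KO_UDCA compared with the other 2. Alternatives were centring each array on its median, quantile normalization, a filter keeping genes above the array median in at least 5 arrays, the mean of all rows of a gene, a variance trend with robust estimation, array weights, a fit to only the groups compared, the numbering pass of the samples as a block, and leaving out each array in turn. The numbering pass separates samples numbered in a first run through the groups from those in a later run. The mean correlation of residuals between arrays of different groups was -0.00246 within a pass and 0.00299 across passes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.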

Results

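Liver expression profiles were obtained from 22 mice of 2 genotypes on 2 diets. Cyp2c70 encodes the mouse cytochrome P450 that makes muricholic acids, so mice without it have a more hydrophobic bile acid pool. The series title names reversal of bile duct disease and biliary fibrosis by UDCA as the question. The first principal component held 26.7% of the variance and the second 7.71%. On the first, KO_chow arrays lay between 15.7 and 53.4, WT_chow between -12.9 and -11.9, WT_UDCA between -13.1 and -9.71 and KO_UDCA between -11.4 and -0.66. KO_chow mice were spread widely, with replicates 2 and 5 at 53.4 and 51.9 and replicates 1 and 4 at 18.6 and 15.7. Correlations between arrays of a group ran from 0.9741 to 0.989 in KO_chow and from 0.9852 to 0.9898 in WT_chow.

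The targeted gene was lower in both knockout groups. Cyp2c70 measured 11.49 ± 0.14 log2 units in WT_chow (SD, n = 5), 11.43 ± 0.14 in WT_UDCA (n = 6), 10.65 ± 0.12 in KO_chow (n = 5) and 10.51 ± 0.17 in KO_UDCA (n = 6), with no overlap between genotypes. It fell 1.78-fold on chow (limma adjusted p = 3.2e-06) and 1.90-fold under UDCA (adjusted p = 7.96e-06). Signal therefore remained in knockout livers. The part of the gene that was deleted and the part the probes read are not given in the sources used here, so the level checks the labels but not the loss of the transcript.

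**Figure D1:**
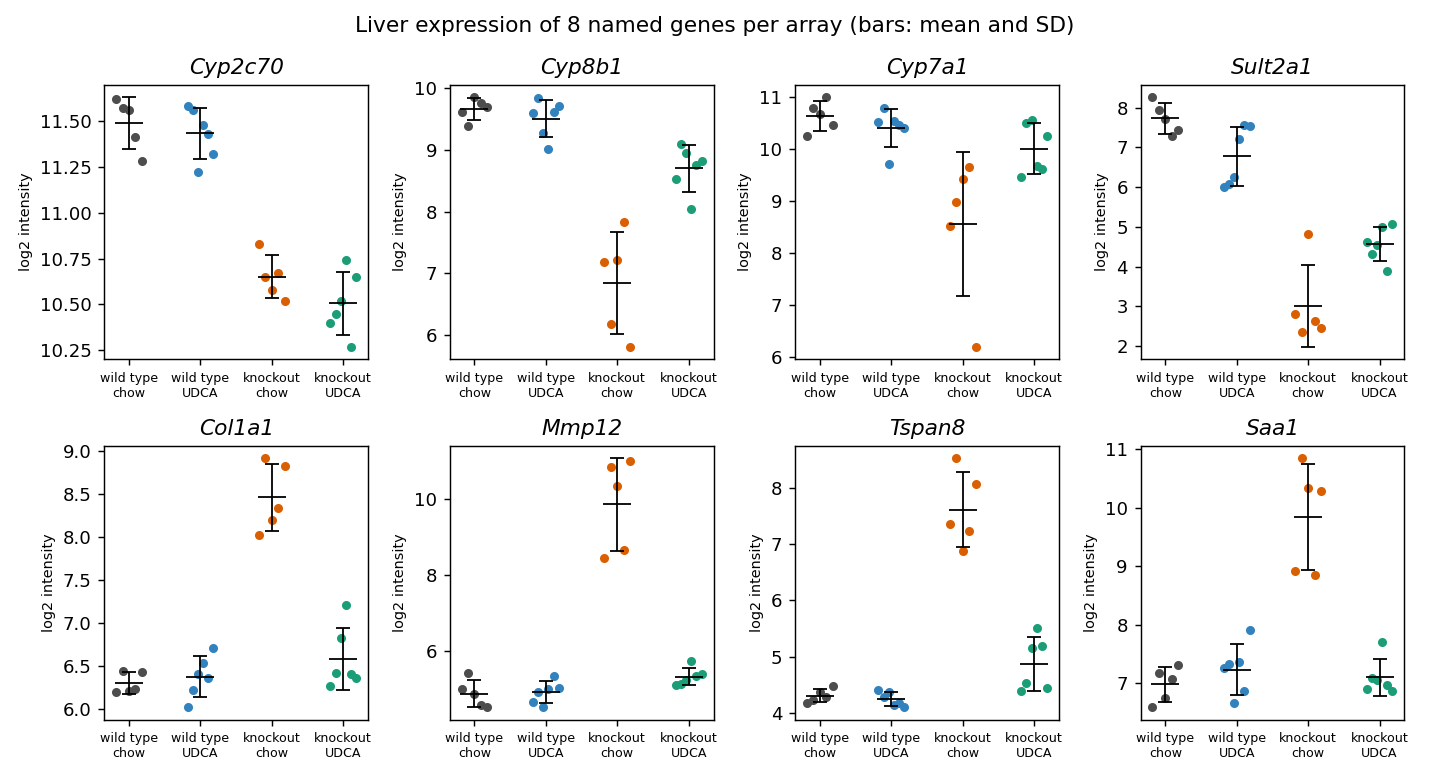
Log2 intensity (vertical axes) of 8 genes in each array, by group; points are mice, and black bars are the mean and SD (n = 5 or 6). Cyp2c70 is lower in both knockout groups, whereas Col1a1, Mmp12, Tspan8 and Saa1 are high in KO_chow and close to wild type in KO_UDCA, and Sult2a1 stays below wild type in KO_UDCA.

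The comparison of KO_chow with WT_chow asks what lacking Cyp2c70 does to the liver on regular chow. Many genes of bile ducts, scar tissue and infiltrating macrophages rose, and some genes of bile acid synthesis, resident macrophages and female-biased hepatocyte metabolism fell (as lists, adjusted p = 0.0926, 0.216 and 0.0231 for these 3 with an estimated correlation). Mmp12, a macrophage elastase, rose 31.8-fold (log2 change 4.99, SE 0.36), the epithelial gene Tspan8 9.84-fold, the collagen gene Col1a1 4.47-fold and the acute phase gene Saa1 7.33-fold, while Cyp8b1, the sterol 12-alpha-hydroxylase, fell 7.04-fold (limma adjusted p at most 8.89e-07 for each). Among the genes named here, the largest rise was that of Sprr1a, a squamous epithelial gene, at 40.9-fold, followed by Mmp12, Ly6d (18.3-fold), Tspan8, Gpnmb (8.13-fold), Mmp13 (7.74-fold), Saa1, Saa2 (7.28-fold), Anxa2 (6.89-fold), Dhrs9 (6.25-fold), and Emp1 and the ileal bile acid transporter Slc10a2 (5.98-fold each). Among genes whose groups did not overlap, the largest falls were those of the bile acid and steroid sulfotransferases Sult2a1 (26.3-fold) and Sult2a2 (12.4-fold), then Cyp8b1, Mup-ps12 (5.95-fold), Sult3a1 (5.20-fold), Elovl3 and Cyp7a1 (4.23-fold each) and Cd163 (3.85-fold). Sult2a1 was dim, below the array median, in every KO_chow mouse (4.815 log2 units in replicate 3, 2.352 to 2.804 in the others). It was also below the array median in KO_UDCA replicates 1, 2, 3 and 5 (3.9 to 4.613). The size of its change in any comparison with a knockout group is therefore not exact. Mup-ps12 was dim in KO_chow as well (3.86 in replicate 5, 2.15 to 2.5 in the others), and in WT_UDCA replicate 4 it read 1.64, below every KO_chow mouse. In all, 3295 of 24011 genes changed at an adjusted p below 0.05, 1847 higher and 1448 lower, and 335 of these at least 2-fold (265 higher, 70 lower). A fit to only these groups called 2008 genes. Without KO_chow replicates 2 and 5, a setting added after the data were seen, 1089 genes were called.

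Markers of cholangiocytes, the cells lining bile ducts, rose together: 13 of 17 measured members rose and 0 fell (14 rose adjusted over the list alone; camera adjusted p = 9.42e-19). Besides Tspan8, Muc1 rose 3.75-fold and Cd24a 2.86-fold, and the ductal keratins Krt19 and Krt7 rose 1.91-fold and 1.42-fold. The call for Krt7 was lost without KO_chow replicates 2 and 5 (adjusted p = 0.226). With an estimated correlation the cholangiocyte list held at a camera adjusted p of 0.00063, and the matrix and portal fibroblast lists below at 0.000727 and 0.0231. Of 32 fibrosis and matrix genes, 29 rose and 0 fell (30 adjusted over the list alone; camera adjusted p = 4e-40), with Mmp12, Mmp13 and the metalloproteinase inhibitor Timp1 (4.65-fold) leading. Portal fibroblast markers rose in 3 of 9, with Dpt at 3.09-fold and Cd34 at 2.23-fold (3 adjusted over the list alone; camera adjusted p = 2.97e-05). Stellate cell markers rose in 5 of 12 and fell in 1, with Cygb at 2.32-fold and the growth factor gene Hgf at 1.65-fold (6 and 2 adjusted over the list alone; camera adjusted p = 0.0024, lost at adjusted p = 0.0853 with an estimated correlation).

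The macrophage lists moved in opposite directions. With an estimated correlation the list of monocyte-derived macrophages held (camera adjusted p = 0.011). Among markers of monocyte-derived macrophages, 11 of 12 rose, led by Gpnmb, Cd14 (5.96-fold) and Lgals3 (4.54-fold) (11 adjusted over the list alone; camera adjusted p = 2.73e-17). Among markers of Kupffer cells, the resident macrophages, 5 of 10 fell, namely Cd163, Fcna (1.91-fold) and Timd4 (1.80-fold) among them, and 0 rose (6 fell adjusted over the list alone; camera adjusted p = 0.000154, but adjusted p = 0.216 with an estimated correlation). Neutrophil markers rose in 6 of 12, with Retnlg at 2.09-fold (7 adjusted over the list alone; camera adjusted p = 4.64e-05, and adjusted p = 0.0872 with an estimated correlation). T and NK cell markers passed the test in 3 of 14, B and plasma cell markers in 0 of 8, and sinusoidal endothelial markers in 3 of 11 (1 higher, 2 lower), and none of these 3 lists was shifted by camera (adjusted p = 0.403, 0.695 and 0.0806). Hepatocyte markers fell in 2 of 13 (camera adjusted p = 0.3), and erythroid genes (0 of 4) and pancreas genes (0 of 6) did not pass (adjusted p = 0.131 and 0.87).

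Inflammation and growth genes rose with them. Cytokine and chemokine genes rose in 13 of 21, led by the monocyte attractant Ccl2 (4.74-fold), Cxcl14 (4.01-fold) and Cxcl10 (3.56-fold) (16 rose and 1 fell adjusted over the list alone; camera adjusted p = 1.4e-10). Cxcl10 lost its call without KO_chow replicates 2 and 5 (adjusted p = 0.0621). Acute phase genes rose in 7 of 14, led by Saa1, Saa2 and Lcn2 (5.46-fold) (7 adjusted over the list alone; camera adjusted p = 7.03e-09, and adjusted p = 0.0661 with an estimated correlation). Cell cycle genes rose in 13 of 18, with the replication helicase gene Mcm6 at 2.25-fold and the topoisomerase gene Top2a at 1.71-fold (13 adjusted over the list alone; camera adjusted p = 2.44e-09). NRF2 targets rose in 6 of 13, with the cystine transporter gene Slc7a11 at 2.43-fold (camera adjusted p = 4.47e-05), and stress response genes rose in 7 of 13 and fell in 1, with Atf3 at 2.43-fold (camera adjusted p = 0.000172). With an estimated correlation the cytokine, cell cycle, NRF2 and stress response lists held (camera adjusted p = 0.0423, 0.0231, 0.0286 and 0.0241). For interferon response genes 0 of 15 passed, although the list shifted up as a whole (median log2 change 0.193, camera adjusted p = 0.0406, but adjusted p = 0.437 with an estimated correlation). The shift rested largely on KO_chow replicate 2, at a list mean of 0.695, against 0.236 in replicate 5 and -0.103, 0.130 and -0.0220 in replicates 1, 3 and 4. It was lost without KO_chow replicate 2 or WT_chow replicate 1, 2 or 4 (adjusted p from 0.0614 to 0.411) and in other settings (up to 0.809).

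Bile acid synthesis genes fell in 9 of 15, led by Cyp8b1 and by Cyp7a1, the rate-limiting enzyme of bile acid synthesis, and 1 rose, the cholesterol 25-hydroxylase gene Ch25h (3.08-fold) (11 fell and 1 rose adjusted over the list alone; camera adjusted p = 8.55e-06, and adjusted p = 0.0926 with an estimated correlation). KO_chow replicate 5 measured 6.21 in Cyp7a1, against 8.52 to 9.67 in the other KO_chow mice, and without it the log2 change of -2.08 became -1.491 (adjusted p = 0.000461) in Cyp7a1, KO_chow vs WT_chow. Transporters went both ways, 3 higher and 6 lower of 15 (4 and 7 adjusted over the list alone; camera adjusted p = 0.118). The uptake transporters Slco1a1 and Slc10a1 fell 3.05-fold and 1.52-fold and the export transporter subunit Slc51b rose 2.34-fold, whereas the bile salt export pump gene Abcb11 changed by -0.19 (SE 0.11, adjusted p = 0.311). Without KO_chow replicates 2 and 5 the calls for Slco1a1 and Slc51b were lost (adjusted p = 0.195 and 0.0575). Among bile acid receptor genes 4 of 12 fell and 1 rose (6 and 2 adjusted over the list alone; camera adjusted p = 0.218), with Nr1i3 2.28-fold lower (adjusted p = 0.0792 without KO_chow replicates 2 and 5) and Klb 1.58-fold lower, and Nr0b2 was at 0.33 (SE 0.23, adjusted p = 0.398). Of the 14 other Cyp2c genes 7 fell, with Cyp2c69 2.05-fold and Cyp2c39 1.81-fold lower (9 fell and 1 rose adjusted over the list alone; camera adjusted p = 5.42e-05, and adjusted p = 0.195 with an estimated correlation). The list mean was -0.722 and -0.737 in KO_chow replicates 2 and 5, against -0.166, -0.0682 and -0.0971 in replicates 1, 3 and 4 and from -0.245 to -0.00172 in KO_UDCA mice. The calls for Cyp2c38, Cyp2c40 and Cyp2c67 were lost without KO_chow replicate 2 or WT_chow replicate 1, for Cyp2c40 and Cyp2c67 also without KO_chow replicate 5 and for Cyp2c40 without WT_chow replicate 2 (adjusted p from 0.0503 to 0.0802, and up to 0.362 without KO_chow replicates 2 and 5). Cyp2c genes are close in sequence, so each value is open to signal from its relatives.

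Female-biased liver genes fell in 9 of 12 and rose in 1, and male-biased genes fell in 6 of 13 and rose in 1 (camera adjusted p = 3.46e-06 and 0.00283, and adjusted p = 0.0231 and 0.147 with an estimated correlation). Sult2a1, the androgen synthesis gene Cyp17a1 (3.19-fold) and Cyp3a16 (5.75-fold) led the female-biased list, and Elovl3 the male-biased list. The call for Cyp3a16 was fragile: it was lost without WT_chow replicate 2, 3 or 4 or KO_chow replicate 1, 2, 4 or 5 (adjusted p from 0.0624 to 0.0996, and 0.187 without KO_chow replicates 2 and 5). Without WT_chow replicate 5 the log2 change of -2.52 became -3.181 in Cyp3a16, KO_chow vs WT_chow. Fatty acid oxidation genes fell in 10 of 17 and rose in 1 (camera adjusted p = 1.76e-05, and adjusted p = 0.216 with an estimated correlation), with Cyp4a14 2.36-fold and Acot1 2.30-fold lower (adjusted p = 0.19 and 0.279 without KO_chow replicates 2 and 5). The call for Acot1 was lost without KO_chow replicate 2, KO_chow replicate 5 or WT_chow replicate 5 (adjusted p from 0.057 to 0.0702). Lipogenesis genes fell in 5 of 17, with Mlxipl 1.61-fold lower, and pericentral genes in 5 of 11, with Tbx3 1.82-fold lower (camera adjusted p = 0.000261 and 3.88e-05, and adjusted p = 0.216 and 0.18 with an estimated correlation). Tbx3 lost its call without WT_chow replicate 1 or 3 or KO_chow replicate 2 or 5 (adjusted p from 0.0598 to 0.089), and Mlxipl in the fit to only these groups (adjusted p = 0.075). Without KO_chow replicates 2 and 5 the adjusted p was 0.336 for Tbx3 and 0.237 for Mlxipl. Immediate early genes rose in 2 of 10, with Klf6 3.11-fold higher (7 adjusted over the list alone; camera adjusted p = 0.000396, but adjusted p = 0.216 with an estimated correlation). Periportal genes fell in 2 of 9 (camera adjusted p = 0.0471, but adjusted p = 0.269 with an estimated correlation), a shift lost without WT_chow replicate 2, 4 or 5 or KO_chow replicate 2, 4 or 5 (adjusted p from 0.0516 to 0.135). Xenobiotic metabolism genes fell in 6 of 18, clock genes in 2 of 14 and p53 targets in 1 of 9, and cholesterol synthesis genes passed in 0 of 18 (camera adjusted p = 0.0583, 0.0645, 0.199 and 0.115).

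**Figure D2:**
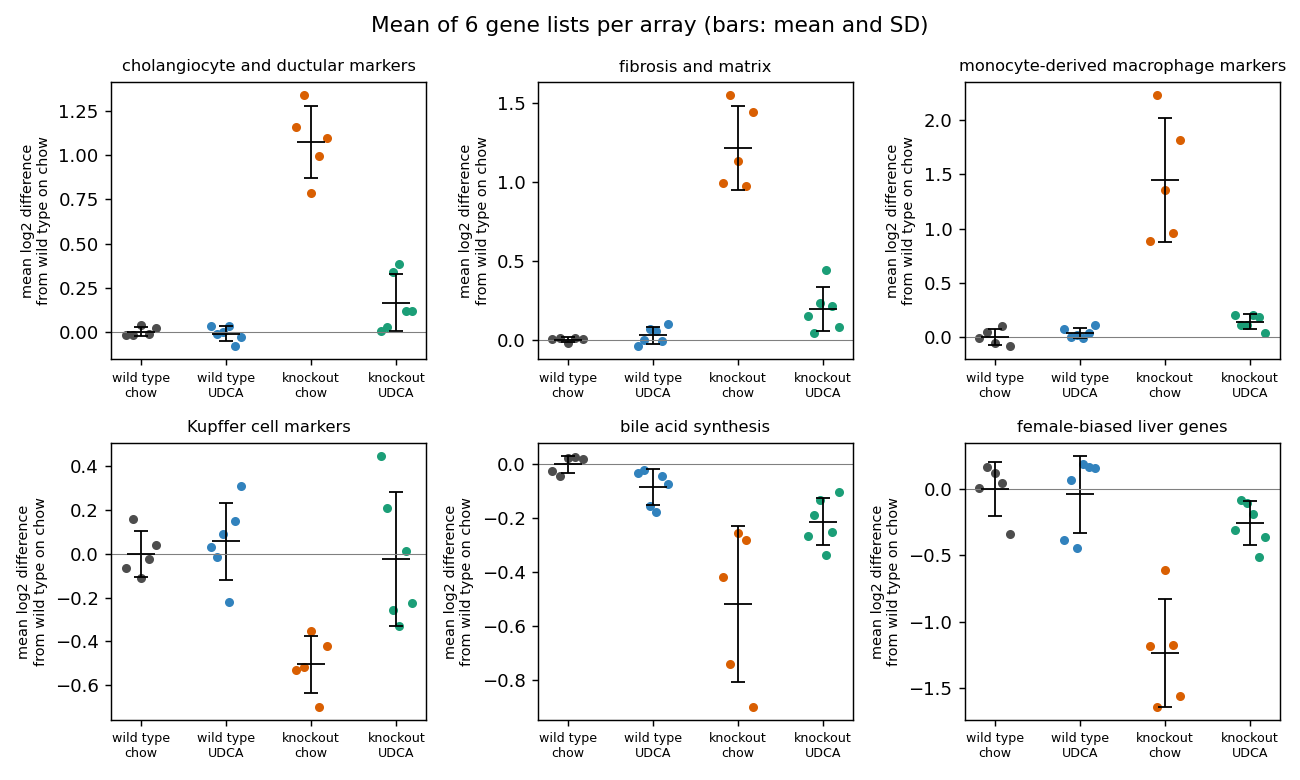
Mean log2 difference from wild type on chow (vertical axes) over the members of 6 gene lists in each array, by group; points are mice, and black bars are the mean and SD (n = 5 or 6). Cholangiocyte, matrix and monocyte-derived macrophage lists are high in KO_chow and Kupffer cell and female-biased lists low, without overlap with KO_UDCA mice. The bile acid synthesis list is lowest in KO_chow replicates 2 and 5, and the other KO_chow mice overlap with or lie close to KO_UDCA mice.

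The comparison of KO_UDCA with KO_chow asks what UDCA does in knockout mice. Of the 1847 genes higher on chow 1243 fell, and of the 1448 lower on chow 833 rose. Sprr1a fell 44.0-fold, Mmp12 23.3-fold, Ly6d 15.6-fold, Gpnmb 7.14-fold, Saa2 7.05-fold, Saa1 6.74-fold, and Mmp13 and Tspan8 6.68-fold each (limma adjusted p at most 7.47e-06). Among genes whose groups did not overlap, the largest rises were those of the leptin receptor gene Lepr (3.75-fold), Hao2 (3.73-fold), Cyp8b1 (3.61-fold), Cyp17a1 (3.09-fold) and Cd163 (2.73-fold), followed by Rgs16, Eci3, Eif4ebp3, Cxcl13, Acpp, Scnn1a and Gstt3 (2.68-fold to 2.02-fold). Groups overlapped for Cyp3a16 (4.96-fold), Sult3a1 (log2 change 1.81), Slco1a1 (3.07-fold) and Sult2a1 (log2 change 1.557, adjusted p = 0.00759), which also rose. Without KO_chow replicates 2 and 5 the calls for Cyp3a16, Slco1a1 and Sult2a1 were lost (adjusted p = 0.247, 0.2 and 0.169), and that for Cyp3a16 was lost in 9 of 11 fits without a single array (adjusted p from 0.0681 to 0.122). In all, 2701 genes changed, 1208 higher and 1493 lower, and 234 at least 2-fold (33 higher, 201 lower). A fit to only these groups called 1454 genes, and 673 were called without KO_chow replicates 2 and 5, where Rgs16 and Cxcl13 lost their calls (adjusted p = 0.0789 and 0.053). Without KO_chow replicate 2 the count was 1652 and without KO_chow replicate 5 it was 1632.

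Cholangiocyte markers fell in 14 of 17 (15 adjusted over the list alone; camera adjusted p = 5.91e-19), with Muc1 2.61-fold, Cd24a 2.41-fold and Krt19 1.60-fold lower. Krt7 fell 1.34-fold, a call lost without KO_chow replicate 1, 2 or 5 or KO_UDCA replicate 1, 4, 5 or 6 (adjusted p from 0.0526 to 0.111, and 0.406 without KO_chow replicates 2 and 5). Fibrosis and matrix genes fell in 28 of 32 (29 adjusted over the list alone; camera adjusted p = 1.36e-36), with Thbs1 4.90-fold and Col1a1 3.69-fold lower. Monocyte-derived macrophage markers fell in 11 of 12 (11 adjusted over the list alone; camera adjusted p = 1.39e-17), with Cd14 4.84-fold and Lgals3 4.44-fold lower, and Kupffer cell markers rose in 5 of 10 (6 adjusted over the list alone; camera adjusted p = 1.66e-05, but adjusted p = 0.191 with an estimated correlation). Sinusoidal endothelial markers rose in 3 of 11 and fell in 0 (5 rose adjusted over the list alone; camera adjusted p = 0.00306, but adjusted p = 0.353 with an estimated correlation). KO_UDCA replicate 1 had the highest mean of both the Kupffer cell (0.448) and the endothelial list (0.536). Cytokine genes fell in 13 of 21, acute phase genes in 6 of 14, cell cycle genes in 10 of 18 and NRF2 targets in 7 of 13 (camera adjusted p = 2.21e-11, 4.36e-09, 2.29e-09 and 1.86e-07, with adjusted p = 0.0618 for the acute phase list with an estimated correlation). With an estimated correlation the cholangiocyte, matrix and macrophage lists held (camera adjusted p = 0.00059, 0.00122 and 0.00894). So did the cytokine, cell cycle and NRF2 lists (camera adjusted p = 0.0333, 0.0215 and 0.00894). Camera shifted 21 lists (8 up, 13 down), of which 9 held with an estimated correlation. Those not described for this comparison were the Cyp2c and periportal lists, up, and the portal fibroblast, stress response, neutrophil, immediate early, stellate cell and interferon lists, down, and of these the portal fibroblast and stress response lists held (adjusted p = 0.0296 and 0.0326, against 0.115 to 0.379 for the others). Stellate cell markers lost the shift without KO_chow replicate 4 or KO_UDCA replicate 2 (adjusted p = 0.0962 and 0.0965), and interferon genes without KO_chow replicate 2 (adjusted p = 0.279). Ccl2 fell 4.57-fold, Lcn2 6.16-fold, Mcm6 2.09-fold and Ugdh, an enzyme of glucuronidation, 2.51-fold.

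Bile acid synthesis genes rose in 4 of 15 and fell in 1 (7 and 1 adjusted over the list alone; camera adjusted p = 0.00123, but adjusted p = 0.234 with an estimated correlation and 0.473 without KO_chow replicates 2 and 5). The list mean lay from -0.337 to -0.104 in KO_UDCA and at -0.743 and -0.902 in KO_chow replicates 2 and 5, but from -0.418 to -0.254 in the other KO_chow mice. Cyp7a1 rose 2.74-fold (adjusted p = 0.0199), a call lost in the fit to only these groups (adjusted p = 0.0955) and without KO_chow replicates 2 and 5 (adjusted p = 0.126). Without KO_chow replicate 5 the log2 change of 1.45 became 0.8632 (adjusted p = 0.0332) in Cyp7a1, KO_UDCA vs KO_chow. Ch25h fell 3.10-fold. Among transporters Slc51b fell 3.77-fold and Abcb1a 2.02-fold and Slc10a1 rose 1.47-fold. Female-biased genes rose in 7 of 12 and fell in 1 (11 and 1 adjusted over the list alone; camera adjusted p = 8.12e-07). Fatty acid oxidation genes rose in 8 of 17 and lipogenesis genes in 5 of 17 (camera adjusted p = 3.5e-05 and 5.34e-07, but adjusted p = 0.259 and 0.115 with an estimated correlation). Cyp2c70 itself changed by -0.15 (SE 0.09, adjusted p = 0.372).

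Set gene by gene against the effect of the knockout on chow, 2076 of the 3295 genes (63.0%) changed in the opposite direction with UDCA, 0 changed in the same direction, and 3283 (99.6%) had the opposite sign. The comparisons share the KO_chow arrays, which alone gave a correlation of -0.524 and a covariance of -0.0101 in simulations of unchanged groups. The observed correlation across genes was -0.883 and the covariance -0.0780, and with the KO_chow arrays divided between the comparisons the correlation lay between -0.712 and -0.537. In that division the comparisons share no arrays, so the simulated correlation of -0.524 is not a reference for it. In simulations in which UDCA changed nothing in knockout mice and the arrays were shared as here, 0.00199% of the genes were called in the opposite direction and 64.45% had the opposite sign. These simulations give every group the same spread, whereas KO_chow mice were more spread. With genes selected on 3 KO_chow arrays and KO_UDCA set against the other 2, from 80.2% to 98.9% had the opposite sign.

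The comparison of KO_UDCA with WT_UDCA asks what the knockout does under UDCA. Sult2a1 stayed 4.61-fold lower in knockout mice and Tafa2, a secreted chemokine-like gene, 1.61-fold lower, besides Cyp2c70 and 1810053B23Rik (1.84-fold lower), a clone of unstated function outside the rule for named genes, chosen after its values were seen. These 4 were the genes called by limma, 0 higher and 4 lower, against 1308 at an unadjusted p below 0.05. Of the 4, Cyp2c70 kept its call in every fit without a single array, whereas the others did not. Sult2a1 lost it without KO_UDCA replicate 2, 3 or 5 or WT_UDCA replicate 4, 5 or 6 (adjusted p from 0.0576 to 0.103), Tafa2 without KO_UDCA replicate 3, 4 or 5 or WT_UDCA replicate 4, 5 or 6 (adjusted p from 0.0595 to 0.104), and 1810053B23Rik without any array but KO_UDCA replicate 1 or 6 (adjusted p from 0.0524 to 0.195, and 0.253 in a fit to only these groups). The count was 1 without KO_UDCA replicate 3 or 5 or WT_UDCA replicate 4, 5 or 6, and 2 without KO_UDCA replicate 2 or 4. With the numbering pass as a block 1 gene was called, and a fit to only these groups called 2.

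Over the 3295 genes changed on chow, the genotype effect under UDCA was 0.118 of that on chow (slope through 0, 95% bootstrap interval 0.0613 to 0.186), and 72.0% of them kept their sign. These genes were selected on the same chow arrays, which tends to lower the slope, and the interval keeps the genes fixed. With genes selected on 3 KO_chow and 3 WT_chow arrays and the chow effect taken from the rest, the slope was 0.1243 to 0.1848 (mean 0.1587). The chow effect then rests on fewer arrays, and error in it also tends to lower the slope, so this value is not free of bias. Camera shifted 6 lists in this comparison (3 up, 3 down), and 0 with an estimated correlation. Fibrosis and matrix genes were slightly higher in KO_UDCA than in WT_UDCA (median log2 difference 0.15, 5 of 32 passing adjusted over the list alone and 0 over all genes; camera adjusted p = 2.11e-08), and so were cholangiocyte markers (median 0.212, 0 of 17; camera adjusted p = 0.00046). Both calls were lost with an estimated correlation (adjusted p = 0.422 for each). Cholesterol synthesis genes were lower (median -0.184, 0 of 18, camera adjusted p = 7.01e-05, but adjusted p = 0.775 with an estimated correlation). Their median on chow was similar (-0.149), although camera did not call it (adjusted p = 0.115). The interaction did not shift this list (median -0.0467, camera adjusted p = 0.623), so the difference is not particular to UDCA. Sinusoidal endothelial markers were higher (median 0.13, against -0.203 on chow), and pericentral and male-biased genes lower (median -0.137 and -0.215), with camera adjusted p = 0.00317, 0.00916 and 0.0191, but adjusted p = 0.806, 0.806 and 0.666 with an estimated correlation. These 3 shifts were lost without single arrays: the endothelial list without KO_UDCA replicate 1 or WT_UDCA replicate 4 (adjusted p = 0.303 and 0.204), the pericentral list without KO_UDCA replicate 4 or 5 or WT_UDCA replicate 5 or 6 (0.0523 to 0.226), and the male-biased list without KO_UDCA replicate 4 or 6 or WT_UDCA replicate 1 or 2 (0.129 to 0.21). Of the 14 other Cyp2c genes 0 passed (median 0.00797, camera adjusted p = 0.928).

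**Figure D3:**
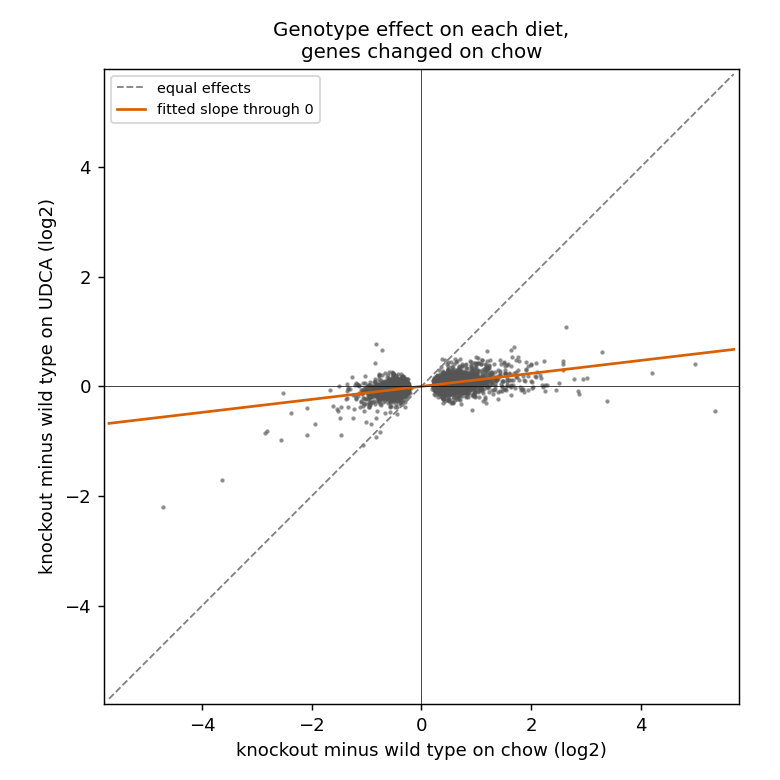
Knockout minus wild type on UDCA (vertical axis, log2) against knockout minus wild type on chow (horizontal axis, log2) for the 3295 genes changed on chow; each point is a gene, the dashed line marks equal effects and the solid line the slope of 0.118. Most points lie near the horizontal line at 0, and Sult2a1 is the point farthest below it, at -2.20 under UDCA.

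The comparison of KO_UDCA with WT_chow sets treated knockout mice against untreated wild type. Sult2a1 was 8.92-fold lower, the fatty acid elongase gene Elovl3 3.90-fold, Cyp2c70 1.97-fold, Tafa2 1.67-fold and Pls1 1.53-fold lower, and Mrc2, a collagen receptor gene, was 1.49-fold higher. These 6 were the genes called by limma (1 higher, 5 lower; 1349 at an unadjusted p below 0.05), and 5 of them had changed the same way on chow. This comparison joins genotype and diet: in WT_UDCA vs WT_chow, Elovl3, Pls1 and Mrc2 lay at -1.074, -0.4358 and 0.3854, the same signs, without being called (adjusted p = 0.461 for each). Tafa2, Mrc2 and Pls1 lost their calls without WT_chow replicate 4 (adjusted p = 0.0505 for each), Tafa2 also without WT_chow replicate 1 or 2 (0.0578 and 0.0549) and Mrc2 without WT_chow replicate 2 (0.065) or 3. In a fit to only these groups the adjusted p was 0.0679 for Tafa2, 0.0926 for Mrc2 and 0.106 for Pls1. The count was 3 without WT_chow replicate 4 and 10 without KO_UDCA replicate 6, and 13 genes were called with array weights and 10 with a variance trend. Camera shifted 9 lists (3 up, 6 down), with fibrosis and matrix up (median 0.198, adjusted p = 1.46e-08) and bile acid synthesis down (median -0.184, adjusted p = 0.00042). The others were the cholangiocyte and monocyte-derived macrophage lists, up, and the pericentral, cholesterol synthesis, Cyp2c, transport and male-biased lists, down. Shifts were lost without WT_chow replicate 1 (transport, cholesterol synthesis and macrophage lists), WT_chow replicate 3 (macrophage and male-biased), KO_UDCA replicate 4 (cholangiocyte, macrophage and male-biased), WT_chow replicate 5 or KO_UDCA replicate 1 or 5 (macrophage), or WT_chow replicate 2 or KO_UDCA replicate 6 (male-biased), with adjusted p from 0.0617 to 0.127. With an estimated correlation 0 of the 9 were shifted (adjusted p from 0.462 to 0.702).

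The comparison of WT_UDCA with WT_chow asks what UDCA does in wild type. No named gene passed: Cyp7a1 differed by -0.23 (SE 0.40), Cyp8b1 by -0.15 (SE 0.26), Abcb11 by -0.29 (SE 0.11) and Col1a1 by 0.07 (SE 0.17), with limma adjusted p at least 0.791 for these 4. Pls1 differed by -0.436 (SE 0.097, adjusted p = 0.461) and Sult2a1 by -0.95 (SE 0.37, adjusted p = 0.823). In the first numbering pass Sult2a1 lay at 6.007 to 6.263 in WT_UDCA (replicates 1 to 3) and at 7.715 to 8.255 in WT_chow. In the second pass it lay at 7.208 to 7.554 in WT_UDCA (replicates 4 to 6) and at 7.285 and 7.444 in WT_chow. The difference in Sult2a1 was thus seen in mice of the first pass only. In all 0 genes were called, against 1338 at an unadjusted p below 0.05, and 1 was called in a fit to only these groups and 1 without WT_chow replicate 1. The list of bile acid and biliary lipid transporters shifted down (median -0.0691, camera adjusted p = 0.00526), a call lost with an estimated correlation (adjusted p = 0.354).

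The interaction asks whether the effect of UDCA differed between genotypes. The difference, knockout minus wild type, was negative for many genes of scar tissue, ducts and inflammation and positive for Cyp8b1 and for female-biased genes as a list. In log2 change it was -5.81 for Sprr1a (SE 0.74), -4.58 for Mmp12 (SE 0.48), -2.68 for Tspan8 (SE 0.32), -1.95 for Col1a1 (SE 0.24), 2.01 for Cyp8b1 (SE 0.37) and 2.51 for Sult2a1 (SE 0.52), with limma adjusted p at most 0.0112. For Sult2a1 the wild-type difference of -0.95, which was not called, makes up part of it. That difference came from mice of the first numbering pass, while WT_UDCA and WT_chow mice of the second pass overlapped. In all 642 genes passed, 144 with a positive and 498 with a negative difference, and 207 without KO_chow replicates 2 and 5, where Sult2a1 lost its call (adjusted p = 0.085). The count was 1028, 301, 1219 and 370 without KO_chow replicate 1, 2, 4 or 5, 394, 415, 404 and 427 without WT_chow replicate 1, 3, 4 or 5, and 425 and 405 without KO_UDCA replicate 3 or 6. Camera shifted 24 lists (11 up, 13 down), of which 9 held with an estimated correlation.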

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

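Of the tests here, those on the hepatocyte share and on shared Cyp2c probes, and the counts without Cyp2c70, were chosen after the results they address were seen.

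Cholangiocyte, matrix and monocyte-derived macrophage markers were higher in KO_chow than in WT_chow, by a mean log2 change of 1.08 (SE 0.0928), 1.22 (SE 0.119) and 1.45 (SE 0.258). A lower share of hepatocytes alone would raise the markers of every other cell type alike. The macrophage list rose by 1.95 (SE 0.245) more than the Kupffer cell list, which lay at -0.505 (SE 0.0754), and B and plasma cell markers lay at -0.0175 (SE 0.0903), which argues against that explanation as the whole cause. More ductal, scar-forming and infiltrating cells, or higher expression in cells already present, may each account for the rise, and whole-liver arrays leave both open.

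Cyp2c genes other than Cyp2c70 were lower in KO_chow. The median level over the genes was taken in each array, and the group means of these medians were compared. The change was -0.793 (SE 0.209) over the 7 that fell (-0.831, -0.941, -0.368, -0.361 and -1.46 in replicates 1 to 5) and -0.546 (SE 0.244) over all 14. It differs from the median of the changes per gene, which was -0.499 over the 14 on chow and 0.00797 under UDCA. Probes shared with Cyp2c70 could give such a fall, and would give it under UDCA too, where Cyp2c70 was lower by as much (-0.928, against -0.835 on chow). Under UDCA the change of the 7 was -0.0172 (SE 0.101), higher by 0.776 (SE 0.232) than on chow, and over all 14, of which 7 were not called, the difference was 0.452 (SE 0.251), which decides nothing. The 7 were picked for their fall, so fallen genes were also picked on 3 KO_chow and 3 WT_chow arrays, at an unadjusted p below 0.05. With the chow change measured on the rest, it was -0.854, against 0.015 under UDCA, a difference of 0.869 (means of 100 divisions). The divisions overlap and gave no SE of their own, so the difference was judged by the SE of 0.232 of the 7. It argues against shared probes as the whole cause for genes that fell. An effect of the disease on chow stays open as a hypothesis and was not tested.

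Under UDCA the genotype effect on the genes changed on chow, Sult2a1 and the matrix genes among them, had a slope of 0.118 on the effect on chow (0.1587 on average with genes selected on other chow arrays). The lowest slope without any 1 array was 0.0993 (without KO_UDCA replicate 4), and of the 462 assignments of the 12 UDCA arrays to 6 and 6 only the real one, 1 in number, gave a slope as large in size, with 0.109 the highest other (two-sided exact permutation p = 0.00216, the smallest it can give). Each KO_UDCA array projected between 0.0447 and 0.208 and each WT_UDCA array between -0.0199 and 0.0171. A small remainder of the chow pattern may persist under UDCA, and a difference between genotypes unrelated to bile duct disease stays open.

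For the counts of changed genes, 100 splits of the arrays into groups of the same sizes were compared, the real split included. Apart from WT_UDCA vs WT_chow, the real split called more genes than any other, 1 in 100, the smallest share this test can give. The counts were 3295 against at most 579 for KO_chow vs WT_chow and 2701 against 136 for KO_UDCA vs KO_chow. They were 4 against 1 for KO_UDCA vs WT_UDCA, 6 against 2 for KO_UDCA vs WT_chow and 642 against 1 for the interaction. For the interaction, diet labels were reassigned within each genotype, which also removes the effect of diet within a genotype. That count therefore speaks on an effect of diet, and cannot decide whether the effect differs between genotypes. Cyp2c70, the targeted gene, is 1 of the 4 and of the 6, and without it the counts were 3 against 1 and 5 against 2. The 4 fell to 1 without KO_UDCA replicate 3 or 5 or WT_UDCA replicate 4, 5 or 6, no more than the highest other split, and the 6 to 3 without WT_chow replicate 4, so these small counts are not sturdy. For WT_UDCA vs WT_chow limma called 0 genes with the real groups (1338 at an unadjusted p below 0.05). All 100 splits call at least 0 genes whatever the data hold, so the comparison says nothing about chance there, and the highest other called 2.

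Single mice stood apart from the rest of their group in 30 of 468 tests of 83 genes and 34 lists, against 23.4 by chance, most often KO_UDCA replicate 4 (5 times). In log2 units, the gene values were as follows. In WT_chow, Slc51b was 4.22, Fcna 7.13 and Gstt3 8.28 in replicate 3, Thbs1 5.48 in replicate 4, Cxcl10 5.71 in replicate 2 and Sprr1a 4.39 in replicate 1. In WT_UDCA, Cyp7a1 was 9.72 and Eif4ebp3 6.99 in replicate 3, Mup-ps12 1.64 in replicate 4 and Acpp 6.85 in replicate 2. In KO_chow, Cd24a was 6.55 and Sult2a1 4.82 in replicate 3, and Mup-ps12 3.86 in replicate 5. In KO_UDCA, Ch25h was 4.02, Cd24a 5.44 and Pls1 4.48 in replicate 2, Krt7 5.35 in replicate 3, and Cxcl14 5.21, Saa1 7.71, Saa2 7.51 and Hao2 9.04 in replicate 4.

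List means stood apart in the same way. In WT_chow, bile acid receptors lay at -0.113 and p53 targets at -0.16 in replicate 2, matrix genes at -0.0245 in replicate 3, and neutrophil markers at 0.0427 and acute phase genes at 0.189 in replicate 5. In WT_UDCA replicate 4, sinusoidal endothelial markers lay at -0.401 and pericentral genes at -0.306. In KO_UDCA, T and NK cell markers lay at 0.317 in replicate 4 and immediate early genes at 0.309 in replicate 2.

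The effect of UDCA differed between genotypes for 47 of the 83 genes of the text, given as the log2 effect in knockout minus that in wild type. Over all genes 642 of 24011 passed. The 83 were picked after the values were seen, under a rule that includes the largest changes, so their higher share follows from the choice. It was lower in knockout mice for Sprr1a (-5.81), Mmp12 (-4.58), Ly6d (-3.95), Saa1 (-3.01), Saa2 (-2.94), Gpnmb (-2.87), Mmp13 (-2.82), Tspan8 (-2.68), Anxa2 (-2.64), Lcn2 (-2.51), Cd14 (-2.28), Timp1 (-2.23), Ccl2 (-2.22), Thbs1 (-2.18), Emp1 (-2.17), Slc10a2 (-2.12), Lgals3 (-2.03), Col1a1 (-1.95), Cxcl14 (-1.91), Klf6 (-1.65), Dhrs9 (-1.57), Muc1 (-1.46), Cd24a (-1.28), Mcm6 (-1.14), Ugdh (-0.973), Dpt (-0.965), Cd34 (-0.946), Cygb (-0.879), Mrc2 (-0.793), Krt19 (-0.69) and Hgf (-0.646). It was higher for Slc10a1 (0.582), Fcna (0.667), Timd4 (0.824), Cyp2c39 (0.947), Gstt3 (0.96), Cyp2c69 (1.01), Acpp (1.13), Scnn1a (1.24), Cd163 (1.26), Lepr and Cxcl13 (1.28 each), Eci3 (1.53), Cyp17a1 (1.61), Sult3a1 (1.89), Cyp8b1 (2.01) and Sult2a1 (2.51). Of the 47 calls 19 were lost in some setting. In some of the 22 fits without 1 array 11 were lost, each of them without KO_chow replicate 2. Lgals3 lost its call in 19 of these fits (adjusted p up to 0.0934), Ccl2 in 18 (0.097), Lepr in 15 (0.0924), Sult3a1, Fcna, Cxcl13 and Gstt3 in 14 each (0.0802, 0.0883, 0.102 and 0.0916) and Timd4 in 6 (0.063). Slc10a1, Cd163 and Klf6 lost theirs in 1 (0.0502, 0.055 and 0.0513).

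The same difference, as a list median, was negative for 13 lists that camera shifted: monocyte-derived macrophage (-1.14), cholangiocyte (-0.964), matrix (-0.836), cytokine (-0.612), NRF2 (-0.558), neutrophil (-0.415), cell cycle (-0.395), acute phase (-0.386), stress response (-0.378), immediate early (-0.374), interferon (-0.199), stellate cell (-0.198) and portal fibroblast (-0.168). It was positive for 11 lists that camera shifted: periportal (0.169), pericentral (0.185), xenobiotic (0.205), transport (0.223), lipogenesis (0.306), sinusoidal endothelial (0.311), bile acid synthesis (0.35), fatty acid oxidation (0.39), Cyp2c (0.415), Kupffer cell (0.517) and female-biased (0.999). Lists that camera did not shift are left out here, whatever the sign of their median. With an estimated correlation 9 of the 24 held (camera adjusted p at most 0.0403). Among the positive lists this was the female-biased list alone. Among the negative ones it was the macrophage, cholangiocyte, matrix, cytokine, NRF2, cell cycle, stress response and portal fibroblast lists. The others were lost (camera adjusted p from 0.0906 to 0.395). The transport, xenobiotic, interferon and periportal lists lost their calls in 12, 11, 4 and 4 of the 22 fits without 1 array (adjusted p up to 0.089, 0.234, 0.234 and 0.0756).

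Among the 958 probe sets without a gene symbol, which no comparison of the report uses, limma called 129 in KO_chow vs WT_chow, 98 in KO_UDCA vs KO_chow and 20 in the interaction.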

How the results depend on the processing

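The setting without KO_chow replicates 2 and 5 was chosen after seeing the data; the others were planned. For the 203 genes named by the rule and 1810053B23Rik, 285 calls were made, of which 79 were lost without some single array, 130 in some setting and 0 reversed. The dim-gene filter gave 275 gene results where the mean of all rows gave 290, and genes it left out are not counted as lost. Of the calls in KO_chow vs WT_chow 24 of 110 were lost without a single array (7 of 79 among the genes of the text), in KO_UDCA vs KO_chow 24 of 103 (11 of 75), in KO_UDCA vs WT_UDCA 3 of 4, in KO_UDCA vs WT_chow 3 of 6 and in the interaction 25 of 62 (11 of 47), so the text names sturdier genes than the rule does. For the genes of the text, the calls lost in some setting were 20 of 79 in KO_chow vs WT_chow, 22 of 75 in KO_UDCA vs KO_chow and 19 of 47 in the interaction. For Abcb11, KO_UDCA vs KO_chow, which was not called, the log2 change ran from -0.1572 (without KO_chow replicate 2) to 0.01326 (without KO_chow replicate 1, adjusted p = 0.962), where its sign reversed. With an estimated correlation the lists shifted numbered 9 for KO_chow vs WT_chow, 9 for KO_UDCA vs KO_chow, 9 for the interaction and 0 for the other comparisons. Fits to only the groups compared called 2008 genes for KO_chow vs WT_chow, 1454 for KO_UDCA vs KO_chow, 2 for KO_UDCA vs WT_UDCA and 1 for WT_UDCA vs WT_chow. Without KO_chow replicates 2 and 5 the counts were 1089, 673 and 207 (interaction) and the slope 0.1704; fewer arrays were fitted. The slope with genes selected on other chow arrays was 0.1587. KO_UDCA vs WT_chow called 10 genes with the dim-gene filter, which tests fewer genes, 10 with a variance trend and 13 with array weights (10 of the genes changed on chow still changed), and the filter shifted 2 lists in WT_UDCA vs WT_chow. With the numbering pass as a block KO_UDCA vs WT_UDCA called 1 gene, 1 of them changed on chow. Apart from these constructions, the cause was not tested. Leaving out 1 array gave 2219 to 3849 genes for KO_chow vs WT_chow, 1632 to 3201 for KO_UDCA vs KO_chow (1652 without KO_chow replicate 2, 1632 without replicate 5), 1 to 4 for KO_UDCA vs WT_UDCA (lowest without KO_UDCA replicate 3), 3 (without WT_chow replicate 4) to 10 (without KO_UDCA replicate 6) for KO_UDCA vs WT_chow, 0 to 1 for WT_UDCA vs WT_chow (1 without WT_chow replicate 1) and 301 to 1219 for the interaction (without KO_chow replicates 2 and 4 in turn). Lists ran from 20 to 24, 20 to 24, 4 to 7, 7 to 13, 1 to 3 (3 without WT_UDCA replicate 5) and 21 to 25 in the same order, the slope from 0.09928 to 0.1381, the share changed back from 52.19% to 68.27%, and the genes still changed from 1 to 4 against WT_UDCA and from 3 to 7 against WT_chow. Centring and quantile normalization left every count of genes and lists within 1.5 times its value.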

Other observations

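All tests in this part were chosen after the data were seen. Genes were grouped into 346 families of at least 8 members by the stem of their symbol. In KO_chow vs WT_chow, the Pex family of peroxisome assembly genes fell in 11 of 14 (median -0.413, camera adjusted p = 4.03e-07) and the Sult family of sulfotransferases in 13 of 21 (median -0.546), while the annexins (Anxa) rose in 7 of 12 (median 0.522, adjusted p = 7.22e-07) and the Itga integrins in 7 of 12 (median 0.377, adjusted p = 0.000275). In KO_UDCA vs KO_chow, Pex genes rose in 8 of 14 and annexins fell in 8 of 12 (adjusted p = 2.01e-05 and 5.56e-07). In KO_UDCA vs WT_UDCA the Sult family stayed lower (median -0.257, 1 of 21 passing, adjusted p = 1.13e-05). Camera shifted 34, 36 and 1 families in these comparisons, and 0 in each with an estimated correlation (adjusted p = 0.327 for Pex, 0.217 for Sult and annexins on chow, and 0.476 for Sult under UDCA).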
